A study of Homo sapiens with 30 samples.

How the data were processed

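The deposited values are log2 expression values per probe set that the authors made with RMA (robust multi-array average, version not given), a method that corrects background, normalises the arrays to each other by quantiles and sums the probes of each set. No further normalisation was applied for the reported values. The 30 arrays had nearly equal medians, from 7.1529 to 7.2051, and the table spanned 2.3002 to 14.6488 with a median of 7.1788.

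The table held 22277 probe sets, of which 62 were array controls. The platform annotation paired 19064 probe sets with 1 gene symbol, 1043 with several and 2108 with none, and 19052 of the first kind had a gene ID in the RefSeq table. No symbol needed updating. For the 4310 genes with more than 1 probe set, the one with the highest mean over the 30 arrays was tested, which left 11963 genes. Probe sets with no symbol or with several were left out of the comparisons. No genome build is stated for the probe sets, so no positions are given. Where other probe sets of a named gene moved much less than the tested one, or the other way, their values are given for comparisons with controls and between the particles. Smaller gaps are not given in every case, nor are other probe sets for the effects between the times. These values cover only other probe sets with a mean over the 30 arrays above the median of the table.

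Each gene was fitted with 1 mean per group (10 groups of 3 arrays) in limma 3.58.1 (R 4.3.3), with moderated variances and two-sided tests. P values were adjusted by the method of Benjamini and Hochberg over all genes within a comparison, with 0.05 as the threshold. "Rose", "fell" and "changed" refer to genes that passed it. Changes are differences of group means on the log2 scale with their standard error (SE) from the shared fit. Group means carry the standard deviation (SD) of the 3 arrays. For any single gene, an exact permutation test of 3 arrays against 3 cannot give a two-sided p under 0.10, so the calls rest on limma's pooled variance. Other packages used were statmod 1.5.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

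The comparisons, the lists, the naming rule and the alternative settings were fixed before the data were examined. Named genes are, per comparison with a control, per comparison of the particles and for the control over time, up to 10 that rose and 10 that fell by the most. They also had no overlap between the 3 and 3 arrays, 1 symbol and a mean in the higher group above the median of the table. Up to 4 called members of each list could be named too, or the member with the largest difference where none passed. Genes of the sex chromosome Y and the X inactivation transcript were left out. Genes named in the comparisons of doses, and in those of the effect between the times, were chosen after their values were seen.

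There were 26 lists of genes, written from general knowledge: NRF2 antioxidant response, metallothioneins and zinc export, heat shock response, unfolded protein and integrated stress response, inflammatory cytokines and NF-kB targets, interferon response, mitosis, DNA replication, p53 targets, cholesterol synthesis and uptake, immediate early and growth factor response, extracellular matrix and TGF-beta response, matrix proteases and plasminogen system, squamous differentiation, basal cell markers, secretory cell and mucin markers, ciliated cell markers, epithelial junctions, aryl hydrocarbon receptor targets, lysosome and autophagy, hypoxia and glycolysis, oxidative phosphorylation, and markers of immune, fibroblast, endothelial and alveolar cells. Each was tested with camera of limma at its preset correlation between genes of 0.01, which compares the list with the other genes. P values were adjusted over the lists and comparisons of a kind: 208 tests of a particle against its control, 104 between the particles and, added after the data were examined, 26 for the control over time. The preset correlation gave 33, 17 and 11 calls. With the correlation estimated from the residuals, 6 of these 61 calls held. They were immediate early genes in MWCNT 100 and TiO2 100 at 1 h, in TiO2 100 at 24 h, in MWCNT 100 against TiO2 100 at 24 h and in the control over time, and aryl hydrocarbon receptor targets in MWCNT 100 against TiO2 100 at 1 h. Fry, which tests whether a list's genes move one way on balance and does not compare them with other genes, gave 35 of the 61. For lists with called members the counts adjusted over the list alone are given as well.

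Agreement of the particles was measured as the correlation and covariance of their changes across the genes, set against 100 simulated draws in which exposed groups equalled the controls they share. The count of genes called with both particles was set against the same draws, a comparison added after the data were examined. Genes are not independent replicates, so no p was attached to these correlations.

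The alternative settings were a filter that left the 7177 genes with a group mean above the median of the table, all non-control probe sets (22215), cyclic loess on top of the authors' values, array weights, a variance model with intensity trend and robust settings, only the compared groups in the fit, the replicate number as a block, and each array of the compared groups left out in turn. Added later, on seeing the values, were the mean of a gene's probe sets, cyclic loess together with leaving out replicate 1 of the 24 h controls, and checks of the list tests and of the particles' overlap without single arrays and after cyclic loess.

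The labels give 3 biological replicates per group and no batch, date or donor. In no comparison did all 3 pairs of arrays with the same number correlate above 0.1 after removing group means, and 12 of the 30 arrays correlated best with an array of their own number, so the arrays were treated as unpaired. No pair of arrays held identical values. Replicate 1 of the 24 h controls stood apart: its mean correlation with its group was 0.9952 and its 3' minus 5' difference for ACTB was 0.8557, against at most 0.6093 elsewhere. It was kept in the reported fits.

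The procedure was tested on simulated data with the real group sizes and, per gene, 1 variance pooled over the groups. It called 94 of 100 genes changed by 0.5, 100 of 100 changed by 1, and 7 unchanged genes (3.48% of calls). It made 0 calls in a comparison simulated without change and called 0 of 26 random lists. Genes and arrays were drawn independently there. The test therefore says nothing of shifts shared by genes, of correlated lists or of groups that differ in spread. Draws without change from the real residuals gave up to 640 genes called higher with both particles, at 10 ug/ml after 24 h.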

Results

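Gene expression was measured with Affymetrix microarrays in human small airway epithelial (SAE) cells, the lining cells of the narrow branches of the lung. The cultures received multi-walled carbon nanotubes (MWCNT, rolled sheets of carbon) or titanium dioxide nanobelts (TiO2, flat fibres of the mineral) at 10 or 100 ug/ml, or neither, for 1 or 24 h. The 10 groups held 3 biological replicates each, 30 arrays in all, and the number of arrays limits the precision. Unexposed controls existed at both times. Values are log2 expression per probe set as deposited, and 11963 genes were compared. Each gene named for the size of its change had its 3 arrays in 1 group all above the 3 in the other.

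**Figure D1:**
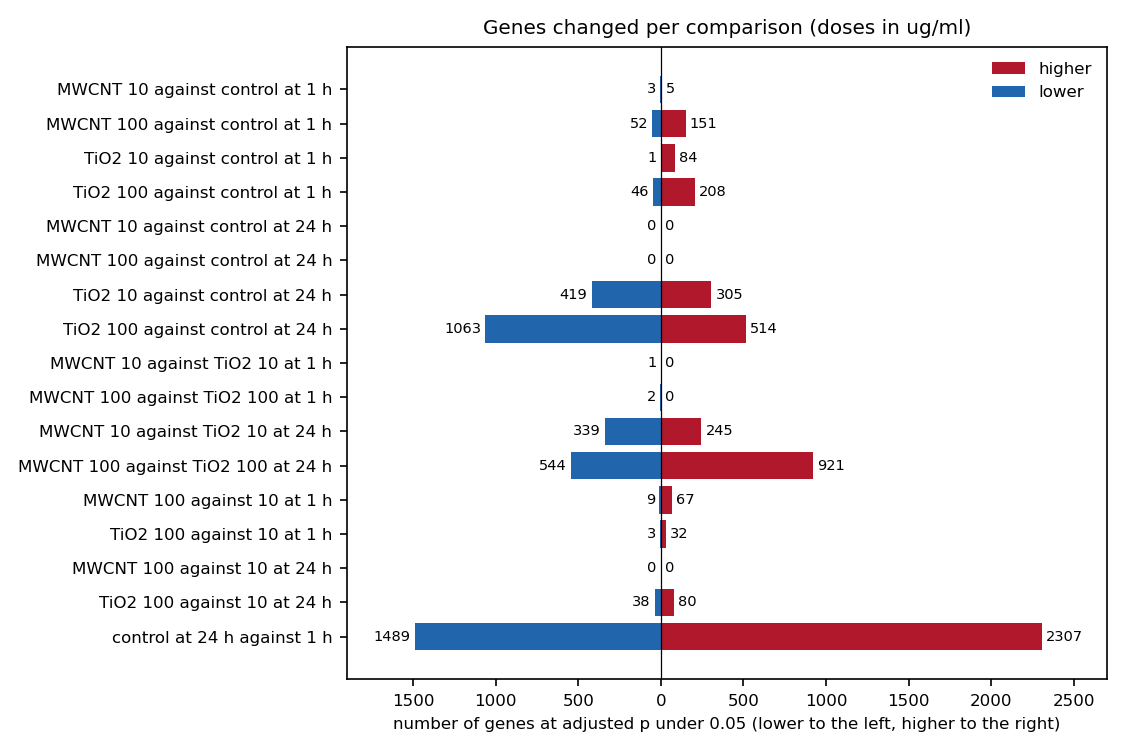
Bars give the number of genes with higher and with lower expression (adjusted p under 0.05) in each comparison of 2 groups of 3 arrays. TiO2 had 254 changed genes at 100 ug/ml after 1 h and 1577 after 24 h, while MWCNT had 203 after 1 h and 0 after 24 h. By more than 1.5-fold, 96 and 29 changed with TiO2, and 73 and 0 with MWCNT. The 24 h counts moved widely between settings of the fit.

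The 1 h comparisons with controls asked which transcripts answer contact with a particle first. After MWCNT at 100 ug/ml, EGR3, a transcription factor switched on within minutes of growth factor or calcium signals, rose by 2.48 ± 0.17 (SE), from 8.90 ± 0.39 to 11.38 ± 0.11 (SD, n = 3, adjusted p = 1.38e-09), a 5.57-fold rise. GLIPR1, a secreted protein induced by p53 and by serum, rose by 2.29 ± 0.17 and FILIP1L, which regulates the cytoskeleton, by 1.90 ± 0.14. NR4A1, an orphan nuclear receptor of the immediate early class, rose by 1.71 ± 0.10 (adjusted p = 2.53e-11) on the tested probe set, while its others moved by -0.11 to 0.23. ANKRD1, a YAP target, rose by 1.68 ± 0.22, TAGLN, an actin-bundling protein, by 1.58 ± 0.18, and THBS1, a matrix glycoprotein that activates TGF-beta, by 1.38 ± 0.17 (adjusted p = 1.17e-05). The cytoskeletal linker EPPK1 rose by 1.25 ± 0.13 and the interferon-inducible GTPase GBP1 by 1.53 ± 0.13.

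The largest falls after MWCNT at 100 ug/ml for 1 h included genes of the aryl hydrocarbon receptor (AhR), a sensor of planar aromatic compounds. CYP1B1, which oxidises such compounds, fell by 1.03 ± 0.24, from 12.06 ± 0.17 to 11.03 ± 0.12 (n = 3, adjusted p = 0.0227), a call kept in 9 of 14 alternatives, and TIPARP, the receptor's feedback inhibitor, by 0.83 ± 0.08 (adjusted p = 2.9e-07). CYP1A1 fell by 0.45 ± 0.10 and the retinaldehyde oxidase ALDH1A3 by 0.28 ± 0.07. Of the 8 measured AhR targets, 4 fell, 0 rose and 4 did not pass, and 4 fell when adjusted over the list alone. With only the compared groups in the fit 2 fell. The list was lower (adjusted p = 0.000133) at the preset correlation, with adjusted p = 0.311 with an estimated correlation. Among metallothioneins and zinc export, the zinc exporter SLC30A1 fell by 0.66 ± 0.07 (adjusted p = 2.88e-07). The metal-binding MT1F fell by 0.48 ± 0.12 and MT2A by 0.43 ± 0.09. In that list of 8, 3 fell, 5 did not pass and 7 fell when adjusted over the list alone (adjusted p = 8.15e-10, adjusted p = 0.311 with an estimated correlation). The estimated correlation between its genes was 0.7211, so its members are not separate evidence. After cyclic loess 2 were called, and 5 with only the compared groups in the fit.

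Immediate early and growth factor genes rose as a group after MWCNT at 100 ug/ml for 1 h, with 7 of 27 higher, 0 lower and 20 not passed, and 12 higher when adjusted over the list alone. The list test gave adjusted p = 7.94e-16, and adjusted p = 9.77e-05 with an estimated correlation. Besides EGR3 and NR4A1, the AP-1 subunit FOSB rose by 1.24 ± 0.14 and KLF6 by 1.00 ± 0.11. Of 21 matrix and TGF-beta genes, 3 rose (TAGLN, THBS1 and CCN2, a YAP and TGF-beta target, by 0.54 ± 0.07), 18 did not pass and 3 rose when adjusted over the list alone (adjusted p = 0.00154, adjusted p = 0.311 with an estimated correlation). Of 23 stress-response genes, ATF3 rose by 0.70 ± 0.11, whereas DDIT4, an inhibitor of mTOR, fell by 0.93 ± 0.10 and DDIT3, the CHOP factor, by 0.29 ± 0.07, with 20 not passed and 1 higher and 2 lower over the list alone. The NF-kB feedback genes TNFAIP3 and NFKBIA rose by 0.58 ± 0.12 and 0.30 ± 0.07, with 24 of 26 inflammatory genes not passed and 3 higher and 1 lower over the list alone. Of 20 hypoxia and glycolysis genes 3 rose, among them PFKFB3 by 0.61 ± 0.09 and the demethylase KDM3A by 0.51 ± 0.06, with 3 higher and 2 lower over the list alone. Neither list passed, and in both the median (-0.0342 and -0.0739) and the mean (0.0085 and 0.0227) had opposite signs. HMOX1, an antioxidant enzyme, fell by 0.26 ± 0.06 as the only one of 19 NRF2 genes to pass, with 1 higher and 3 lower over the list alone. Cholesterol genes were lower, with EBP and FDPS 2 of 16 called and 2 over the list alone (adjusted p = 0.0374, adjusted p = 0.701 with an estimated correlation), as was oxidative phosphorylation with 0 of 22 (0 over the list alone) and median -0.0515 (adjusted p = 0.0466, adjusted p = 0.634 with an estimated correlation), a call lost after cyclic loess and at adjusted p = 0.0526 with the replicate block. With only the compared groups in the fit 0 cholesterol genes were called. In all, 203 genes changed, 151 higher and 52 lower, 73 of them by more than 1.5-fold, with 182 higher and 97 lower under the filter on dim genes. Leaving out 1 array gave 120 and 97 genes without replicates 1 and 2 of the controls, and 118 and 91 without replicates 2 and 3 of the MWCNT group.

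At 10 ug/ml MWCNT for 1 h, EGR3 rose by 1.14 ± 0.17, to 10.04 ± 0.25 (n = 3, adjusted p = 0.00382), and TIPARP fell by 0.60 ± 0.08, to 11.95 ± 0.04 (adjusted p = 0.00089). KLF7, a transcription factor, rose by 0.53 ± 0.07 and VCL, which anchors actin to adhesions, by 0.31 ± 0.06. GLIPR1 rose by 0.89 ± 0.17, a call kept in 6 of 14 alternatives. CDC42EP2, which shapes the cell cortex, fell by 0.40 ± 0.08. These were among 8 changed genes, 5 higher and 3 lower. The count was 5, 2 and 16 without control replicates 1, 2 and 3, and 4, 2 and 3 without MWCNT replicates 1, 2 and 3. AhR targets were lower as a list, with TIPARP alone of 8 past the threshold and 3 adjusted over the list alone (adjusted p = 0.00118, adjusted p = 0.404 with an estimated correlation). Mitosis genes were higher (0 of 26 called, median 0.094, adjusted p = 0.00118, adjusted p = 0.625 with an estimated correlation). Metallothioneins were lower (0 of 8 called, median -0.1526, adjusted p = 0.0319, adjusted p = 0.724 with an estimated correlation). Cholesterol genes were lower too (0 of 16 called, 2 over the list alone, adjusted p = 0.039, adjusted p = 0.701 with an estimated correlation).

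**Figure D2:**
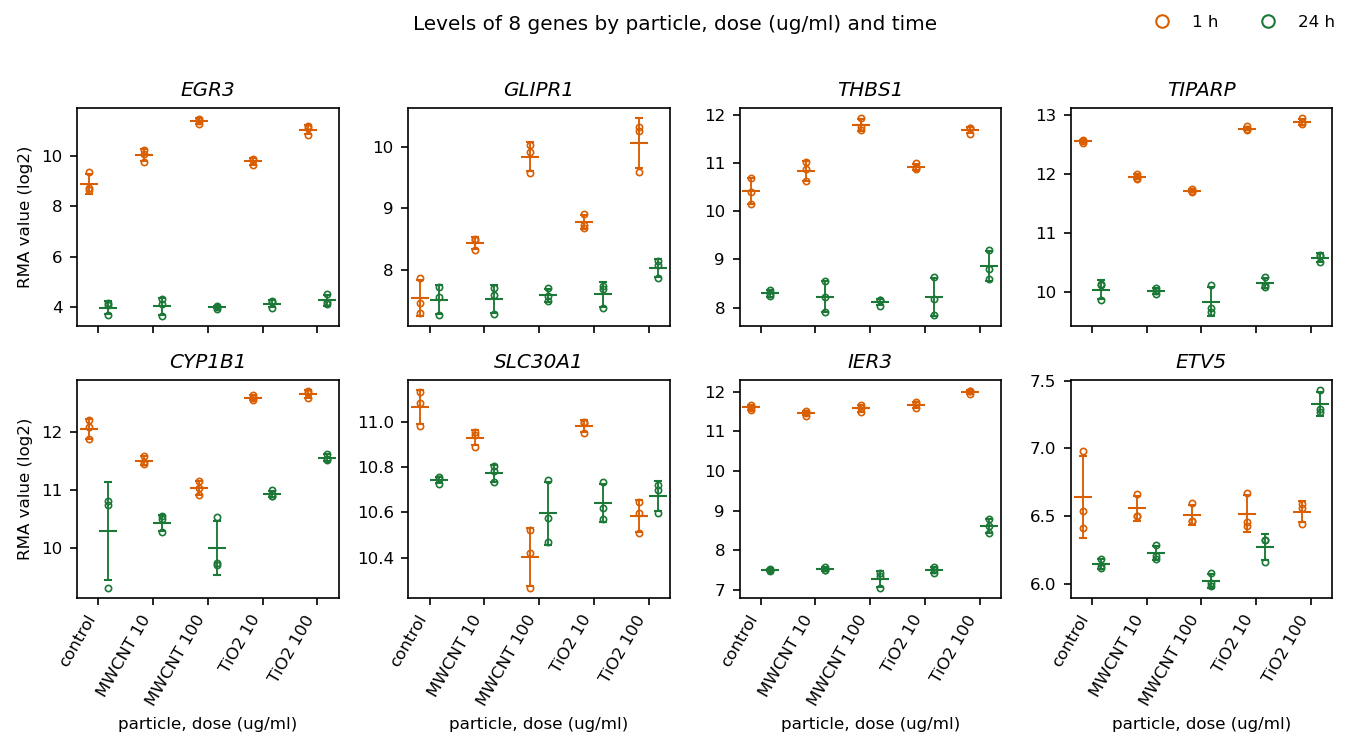
Open circles give log2 expression per array, dashes the group mean and bars the SD (3 arrays per group), in orange for 1 h and green for 24 h, for 8 genes. EGR3 reached 11.38 with MWCNT and 11.04 with TiO2 at 100 ug/ml after 1 h against 8.90 in the controls, and IER3 reached 8.61 with TiO2 at 100 ug/ml after 24 h against 7.51.

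After TiO2 at 100 ug/ml for 1 h many of the same genes rose. GLIPR1 rose by 2.50 ± 0.17, from 7.55 ± 0.29 to 10.05 ± 0.41 (n = 3, adjusted p = 4.58e-10), EGR3 by 2.14 ± 0.17 (adjusted p = 1.86e-08), ANKRD1 by 1.79 ± 0.22 and FILIP1L by 1.60 ± 0.14. TAGLN rose by 1.59 ± 0.18, THBS1 by 1.28 ± 0.17 and FOSB by 1.27 ± 0.14. NR4A1 rose by 1.57 ± 0.10 on the tested probe set, and its others moved by -0.07 to 0.44. Falls were smaller: DDIT4 by 0.54 ± 0.10, SLC30A1 by 0.48 ± 0.07 (adjusted p = 4.97e-05), DDIT3 by 0.38 ± 0.07, the stress hormone GDF15 by 0.34 ± 0.08 and HMOX1 by 0.30 ± 0.06 (adjusted p = 0.00294). TIPARP rose, by 0.33 ± 0.08 (adjusted p = 0.0266), with 7 of 8 AhR targets not passed and 1 higher over the list alone. In total 254 genes changed, 208 higher and 46 lower, 96 by more than 1.5-fold. The lower ones numbered 155 without TiO2 replicate 2, 88 with the filter on dim genes, 27 after cyclic loess and 4 with only the compared groups in the fit. Of the 208, 73 had further probe sets with a mean above the median of the table. For these 73 the median change was 0.5423 on the tested sets and 0.1416 on the others. The count was 144 and 143 without control replicates 1 and 2 and 145 without TiO2 replicate 3.

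Among lists after TiO2 at 100 ug/ml for 1 h, 9 of 27 immediate early genes rose, 0 fell and 18 did not pass, with 14 higher and 1 lower adjusted over the list alone (adjusted p = 8.89e-22, adjusted p = 1.68e-05 with an estimated correlation). With only the compared groups in the fit 5 of the 27 were called. KLF6 rose by 1.23 ± 0.11, and ATF3 of the stress list by 0.86 ± 0.11. Of 21 matrix genes 3 rose (TAGLN, THBS1, CCN2), also 3 over the list alone. Their median was -0.0053 and their mean 0.1485 with the test pointing up (adjusted p = 0.0149, adjusted p = 0.443 with an estimated correlation). Metallothioneins were lower, with SLC30A1 alone of 8 called and 2 lower over the list alone (adjusted p = 0.000284, adjusted p = 0.625 with an estimated correlation). Lysosome genes were lower by a median of 0.0814, with 0 of 23 called and 3 lower over the list alone (adjusted p = 0.0319, adjusted p = 0.404 with an estimated correlation), a call lost after cyclic loess. The adhesion receptor ICAM1 rose by 0.25 ± 0.06 and NFKBIA by 0.30 ± 0.07, the 2 of 26 inflammatory genes to pass, with 5 adjusted over the list alone. IRF9, a subunit of the interferon-activated factor, fell by 0.26 ± 0.06 as 1 of 25 interferon genes, with 1 higher and 3 lower over the list alone.

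At 10 ug/ml TiO2 for 1 h, GLIPR1 rose by 1.23 ± 0.17 (n = 3, adjusted p = 0.00099), KLF6 by 0.78 ± 0.11 (adjusted p = 0.00134), EGR3 by 0.88 ± 0.17 (adjusted p = 0.0127) and NR4A1 by 0.49 ± 0.10, with its other probe sets at -0.01 to 0.02. The zinc finger gene ZNF12 rose by 1.38 ± 0.25, the chromatin remodeller HELLS by 1.30 ± 0.24, the sulfate transporter SLC26A2 by 1.19 ± 0.19 and the basement membrane collagen COL4A4 by 1.16 ± 0.20. TTF1, of transcription termination, rose by 1.09 ± 0.19 and MTDH by 1.08 ± 0.20, while their other probe sets stood at 0.02 for TTF1 and at -0.05 to -0.02 for MTDH. NKTR rose by 1.17 ± 0.23, with other probe sets from 0.06 to 1.39. Immediate early genes were higher with 3 of 27 called, 24 not passed and 4 over the list alone (adjusted p = 0.00118, adjusted p = 0.21 with an estimated correlation). In all 85 genes changed, 84 higher and 1 lower. Of the 84, 31 had further probe sets with a mean above the median of the table. For these 31 the median change was 0.7257 on the tested sets and 0.0905 on the others. The count was 14 and 14 without control replicates 1 and 2, and 14, 48 and 25 without TiO2 replicates 1, 2 and 3.

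Whether the particles act alike at 1 h was asked across genes and by testing them against each other. At 100 ug/ml, 120 genes were higher with both particles and 19 lower with both. In 100 draws without change that share the controls in the same way the means were 0 and 0.07 and the highest 0 and 5. Of the 84 genes higher with TiO2 at 10 ug/ml, 54 were higher with MWCNT and 80 with TiO2 at 100 ug/ml. All these comparisons use the same 1 h controls, and the 84 were chosen as higher than them. How far the level of these controls adds to the shared count cannot be told from this. TIPARP was the 1 gene called in opposite directions. The changes correlated across genes at 0.747, within the range that shared controls alone gave (mean 0.448, -0.42 to 0.914), and genes are not independent replicates. The correlation at 10 ug/ml was 0.529 against a simulated mean of 0.471.

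Tested directly at 1 h, AhR targets were lower with MWCNT than with TiO2. At 100 ug/ml CYP1B1 differed by -1.63 ± 0.24, at 11.03 ± 0.12 against 12.67 ± 0.07 (n = 3, adjusted p = 0.00305), and TIPARP by -1.17 ± 0.08 (adjusted p = 4.2e-09). These were the 2 genes that differed. TIPARP was the only one at 10 ug/ml, at -0.82 ± 0.08 (adjusted p = 6.42e-06), with 3 genes after cyclic loess, 1 higher and 2 lower. The AhR list was lower at 100 ug/ml, with 2 of 8 called, 6 not passed and 5 over the list alone (adjusted p = 2.95e-10, adjusted p = 0.0213 with an estimated correlation). The lower dose had 1 of 8 called and 4 over the list alone (adjusted p = 1.88e-06, adjusted p = 0.122 with an estimated correlation). Cholesterol genes were lower with MWCNT at 100 ug/ml (0 of 16 called, 4 over the list alone, adjusted p = 4.9e-06, adjusted p = 0.212 with an estimated correlation) and at 10 ug/ml (0 called, 1 over the list alone, adjusted p = 0.00125, adjusted p = 0.4 with an estimated correlation). Metallothioneins were lower at 100 ug/ml (0 of 8 called, adjusted p = 0.000563, adjusted p = 0.495 with an estimated correlation). Mitosis genes were higher at 10 ug/ml (0 of 26, adjusted p = 6.2e-05, adjusted p = 0.386 with an estimated correlation) and squamous genes lower (0 of 18, adjusted p = 0.0144, adjusted p = 0.412 with an estimated correlation), the latter lost after cyclic loess.

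Between the doses at 1 h, 76 genes differed for MWCNT, 67 higher and 9 lower at 100 than at 10 ug/ml. FILIP1L was higher by 1.42 ± 0.14, GLIPR1 by 1.40 ± 0.17, EGR3 by 1.34 ± 0.17 and NR4A1 by 1.34 ± 0.10, and the coagulation starter F3 by 0.86 ± 0.11. DDIT4 was lower by 0.75 ± 0.10 and SLC30A1 by 0.53 ± 0.07. For TiO2, 35 genes differed, 32 higher and 3 lower. GLIPR1 was higher by 1.27 ± 0.17, EGR3 by 1.26 ± 0.17, FILIP1L by 1.25 ± 0.14 and NR4A1 by 1.08 ± 0.10, and the 3 that fell were DDIT4 (0.45 ± 0.10), SLC30A1 (0.40 ± 0.07) and TXNIP, an inhibitor of thioredoxin (0.21 ± 0.05). All these were chosen after their values were seen. The other NR4A1 probe sets moved by only -0.11 to 0.23 with MWCNT and -0.07 to 0.44 with TiO2 at 100 ug/ml against controls. The MWCNT count was 40 and 46 without replicates 1 and 3 at 10 ug/ml and 47 without replicate 3 at 100, and the TiO2 count was 23 and 21 without replicates 1 and 2 at 10 ug/ml.

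At 24 h the same questions were asked of later responses. EGR3 and GLIPR1 after MWCNT at 100 ug/ml differed from controls by 0.01 and 0.08 and did not pass, genes looked up for their rise at 1 h, with EGR3 near background. Neither did CYP1B1 at -0.30 ± 0.24 (adjusted p = 0.986, and -0.7868 with adjusted p = 0.123 without control replicate 1), the feedback inhibitor SPRY2 at -0.35 ± 0.09 (adjusted p = 0.799), the keratin KRT16 at -0.27 ± 0.07 (adjusted p = 0.84), or the chemokine CXCL8 at 0.37 ± 0.30 (adjusted p = 0.986). The count by limma was 0 genes, with 661 at an unadjusted p under 0.05 and a smallest adjusted p of 0.735. It was 1 without MWCNT replicate 1 and 722 with array weights. The lower dose gave 0 by limma, with 389 at an unadjusted p under 0.05, a smallest adjusted p of 0.915 and 8 genes with array weights. There the interferon-induced IFIT1 stood at -0.31 ± 0.10 and the membrane mucin MUC4 at 0.25 ± 0.09, neither passed.

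List tests at 24 h with MWCNT at 100 ug/ml found metallothioneins lower, with a median of -0.2191 (-0.3822 without control replicate 1) and MT1M at -0.34 ± 0.17 (0 of 8 called, 0 over the list alone, adjusted p = 4.4e-05, adjusted p = 0.54 with an estimated correlation). Cholesterol genes were lower, with the sterol sensor INSIG1 at -0.31 ± 0.12 (0 of 16, 0 over the list alone, adjusted p = 0.0173, adjusted p = 0.642 with an estimated correlation). Mitosis genes were lower, with DLGAP5 at -0.22 ± 0.12 (0 of 26, 0 over the list alone, adjusted p = 0.0231, adjusted p = 0.716 with an estimated correlation), and so were AhR targets, with a median of -0.0856 (-0.2027 without control replicate 1, 0 of 8, 0 over the list alone, adjusted p = 0.0466, adjusted p = 0.642 with an estimated correlation, adjusted p = 0.0566 with the replicate block). Cholesterol genes were lower at 10 ug/ml, with HMGCS1, of sterol synthesis, at -0.15 ± 0.09 (0 of 16, 0 over the list alone, adjusted p = 0.039, adjusted p = 0.701 with an estimated correlation).

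After TiO2 at 100 ug/ml for 24 h the largest rises included several genes of growth factor signalling and its feedback. That grouping was read from the genes themselves and was not tested as such. ETV5, an ETS factor induced through ERK, rose by 1.18 ± 0.10, from 6.14 ± 0.04 to 7.33 ± 0.09 (n = 3, adjusted p = 2.45e-08), and IER3, an early survival gene, by 1.11 ± 0.08, from 7.51 ± 0.03 to 8.61 ± 0.18 (adjusted p = 5.54e-09). ABCC3, an efflux pump of conjugates, rose by 0.89 ± 0.05 (adjusted p = 1.42e-10). DUSP6, a phosphatase of ERK, rose by 0.71 ± 0.13, SPRED2, an inhibitor of RAS signalling, by 0.63 ± 0.08 and the VEGF and semaphorin receptor NRP1 by 0.63 ± 0.13. The secreted chitinase-like protein CHI3L1 rose by 0.64 ± 0.10 (adjusted p = 0.000349). CYP1B1 rose by 1.28 ± 0.24 (adjusted p = 0.00228) from controls that spread widely, at 10.28 ± 0.85, and by 0.7873 (adjusted p = 0.00392) without control replicate 1. TIPARP rose by 0.54 ± 0.08 (adjusted p = 0.000292).

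At 24 h with TiO2 at 100 ug/ml, ANO2, a calcium-gated chloride channel, fell by 0.80 ± 0.06 (adjusted p = 2.45e-08), TNNC1, a calcium sensor of muscle, by 0.75 ± 0.10 and the glutamate transporter SLC1A1 by 0.73 ± 0.10. The gap junction gene GJA1 fell by 0.67 ± 0.09 and the water channel AQP3 by 0.60 ± 0.08, with other AQP3 probe sets at -0.10 to 0.12. MUC1, a membrane mucin, fell by 0.40 ± 0.05 (adjusted p = 9.07e-05), E-cadherin (CDH1) by 0.39 ± 0.08 and the tight junction claudin CLDN7 by 0.22 ± 0.05. In all 1577 genes changed, 514 higher and 1063 lower, but 29 by more than 1.5-fold. After cyclic loess there were 803, 444 higher and 359 lower. The filter on dim genes gave 277 higher and 1283 lower, and only the compared groups in the fit gave 16 genes, 11 higher and 5 lower. The count was 876 without control replicate 1, and 884 and 718 without TiO2 replicates 1 and 3.

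Immediate early genes were higher as a list at 24 h with TiO2 at 100 ug/ml: 12 of 27 rose, 0 fell and 15 did not pass, with 14 higher over the list alone (adjusted p = 2.81e-10, adjusted p = 0.00121 with an estimated correlation). JUN rose by 0.56 ± 0.12 and PHLDA1 by 0.53 ± 0.13, with other PHLDA1 probe sets at 0.20 to 0.24. AhR targets were higher, with 4 of 8 called (CYP1B1, TIPARP, CYP1A1 by 0.40 ± 0.10 and NFE2L2 by 0.31 ± 0.07) and 4 higher and 1 lower over the list alone (adjusted p = 0.00118, adjusted p = 0.404 with an estimated correlation). Without control replicate 1 CYP1A1 did not pass. Metallothioneins were higher, with 4 of 8 called, 4 over the list alone, and MT1X by 0.48 ± 0.11 and MT1G by 0.42 ± 0.08 (adjusted p = 0.00611, adjusted p = 0.701 with an estimated correlation), a call at adjusted p = 0.179 without control replicate 1, where 2 were called and the median went from 0.297 to 0.1314. Matrix genes were higher with 6 of 21 called, 6 over the list alone, among them TGFBI by 0.31 ± 0.05 and COL1A1 by 0.35 ± 0.10 (adjusted p = 0.0149, adjusted p = 0.443 with an estimated correlation). Without control replicate 1, 3 of the 21 were called, COL1A1 not among them, and the median went from 0.0599 to 0.1719. Matrix proteases had 3 of 16 higher, 5 over the list alone, with the gelatinase MMP2 by 0.43 ± 0.09 (adjusted p = 0.0374, adjusted p = 0.54 with an estimated correlation). Inflammatory genes had 3 higher and 1 lower of 26, also over the list alone. The monocyte attractant CCL2 rose by 0.51 ± 0.10 and LCN2 fell by 0.31 ± 0.08 (adjusted p = 0.0466, adjusted p = 0.634 with an estimated correlation), with 5 higher and 0 lower without control replicate 1. With only the compared groups in the fit, 1 of the 27 immediate early genes was called and 0 in the other 5 lists of this paragraph.

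Secretory markers at 24 h with TiO2 at 100 ug/ml had 3 higher and 1 lower of 13, and 5 and 1 over the list alone, with MUC5B, a gel-forming mucin, higher by 0.32 ± 0.09 and MUC1 lower (adjusted p = 0.0374, adjusted p = 0.54 with an estimated correlation). Squamous genes had 2 higher and 1 lower of 18, and 6 and 2 over the list alone (adjusted p = 0.039, adjusted p = 0.634 with an estimated correlation). Of 25 interferon genes 6 were lower, 1 higher and 18 not passed, and 8 and 1 over the list alone, with USP18 down by 0.40 ± 0.10 and ISG15 by 0.32 ± 0.08, but the list did not pass (adjusted p = 0.326). In the NRF2 list, the quinone reductase NQO1 rose by 0.28 ± 0.08 while the cystine transporter SLC7A11 fell by 0.32 ± 0.06, with 3 higher and 1 lower over the list alone (adjusted p = 0.656 for the list, median -0.0047, mean 0.0021). Of 23 stress genes 3 fell, STC2 by 0.27 ± 0.06, ASNS by 0.17 ± 0.03 and DDIT3 by 0.21 ± 0.07, with 3 lower over the list alone. Another STC2 probe set moved by -0.09. The p53 targets FAS and CDKN1A rose by 0.25 ± 0.06 and 0.18 ± 0.06, with 15 of 17 not passed and 2 higher over the list alone. After cyclic loess the inflammatory, protease, squamous and secretory lists did not pass, and without control replicate 1 the secretory list had adjusted p = 0.071. With only the compared groups in the fit 0 secretory and 0 squamous genes were called. Secretory risers went from 3 to 1 after cyclic loess and to 1 without control replicate 1, where MUC5B, ISG15, NQO1, DDIT3 and CDKN1A did not pass either.

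At 10 ug/ml TiO2 for 24 h changes were small. SLC1A1 fell by 0.51 ± 0.10, from 7.27 ± 0.05 to 6.76 ± 0.09 (n = 3, adjusted p = 0.0158), ZNF365 by 0.48 ± 0.08 and the GATA-type repressor TRPS1 by 0.45 ± 0.09. The receptor genes EPOR and AVPR1B rose by 0.48 ± 0.11 and 0.44 ± 0.09, and FOSB by 0.61 ± 0.14 at a low level, 6.37 ± 0.06. CDH1 fell by 0.38 ± 0.08. Squamous genes were higher with 6 of 18 called, 12 not passed and 9 over the list alone. After cyclic loess 1 of the 18 was called, without control replicate 1 also 1, with only the compared groups in the fit 0 and with the mean of probe sets 2. Corneodesmosin (CDSN) rose by 0.50 ± 0.11 and the protease KLK7 by 0.46 ± 0.13 (adjusted p = 0.000103, adjusted p = 0.311 with an estimated correlation). Metallothioneins were higher by a median of 0.2198 (0 of 8 called, 0 over the list alone, adjusted p = 0.0366, adjusted p = 0.724 with an estimated correlation), with a median of 0.0623 and adjusted p = 0.639 without control replicate 1. Also higher were matrix proteases (MMP9 of 16 called, by 0.31 ± 0.09, 4 over the list alone, adjusted p = 0.0397, adjusted p = 0.54 with an estimated correlation), secretory markers (the antibody transporter PIGR of 13 called, by 0.39 ± 0.10, 1 over the list alone, adjusted p = 0.039, adjusted p = 0.54 with an estimated correlation) and ciliated cell markers (0 of 7, 0 over the list alone, adjusted p = 0.042, adjusted p = 0.404 with an estimated correlation). Without control replicate 1 the secretory and ciliated lists had adjusted p = 0.06 and 0.0835, and after cyclic loess the protease, secretory and ciliated lists did not pass. Without that array EPOR, TRPS1, FOSB, CDH1, KLK7, MMP9 and PIGR did not pass.

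In all, 724 genes changed with TiO2 at 10 ug/ml for 24 h, 305 higher and 419 lower, but 3 by more than 1.5-fold, with a median change of 0.2898 in size. After cyclic loess there were 177, 112 higher and 65 lower. The filter on dim genes gave 100 higher and 595 lower, and limma with only the compared groups in the fit gave 0 genes. The count was 74 without control replicate 1, and 243 and 82 without TiO2 replicates 1 and 3. IFIT1 and IFI44 of the interferon list fell by 0.35 ± 0.10 and 0.35 ± 0.09, with 23 of 25 not passed and 3 lower over the list alone, and neither passed without control replicate 1.

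**Figure D3:**
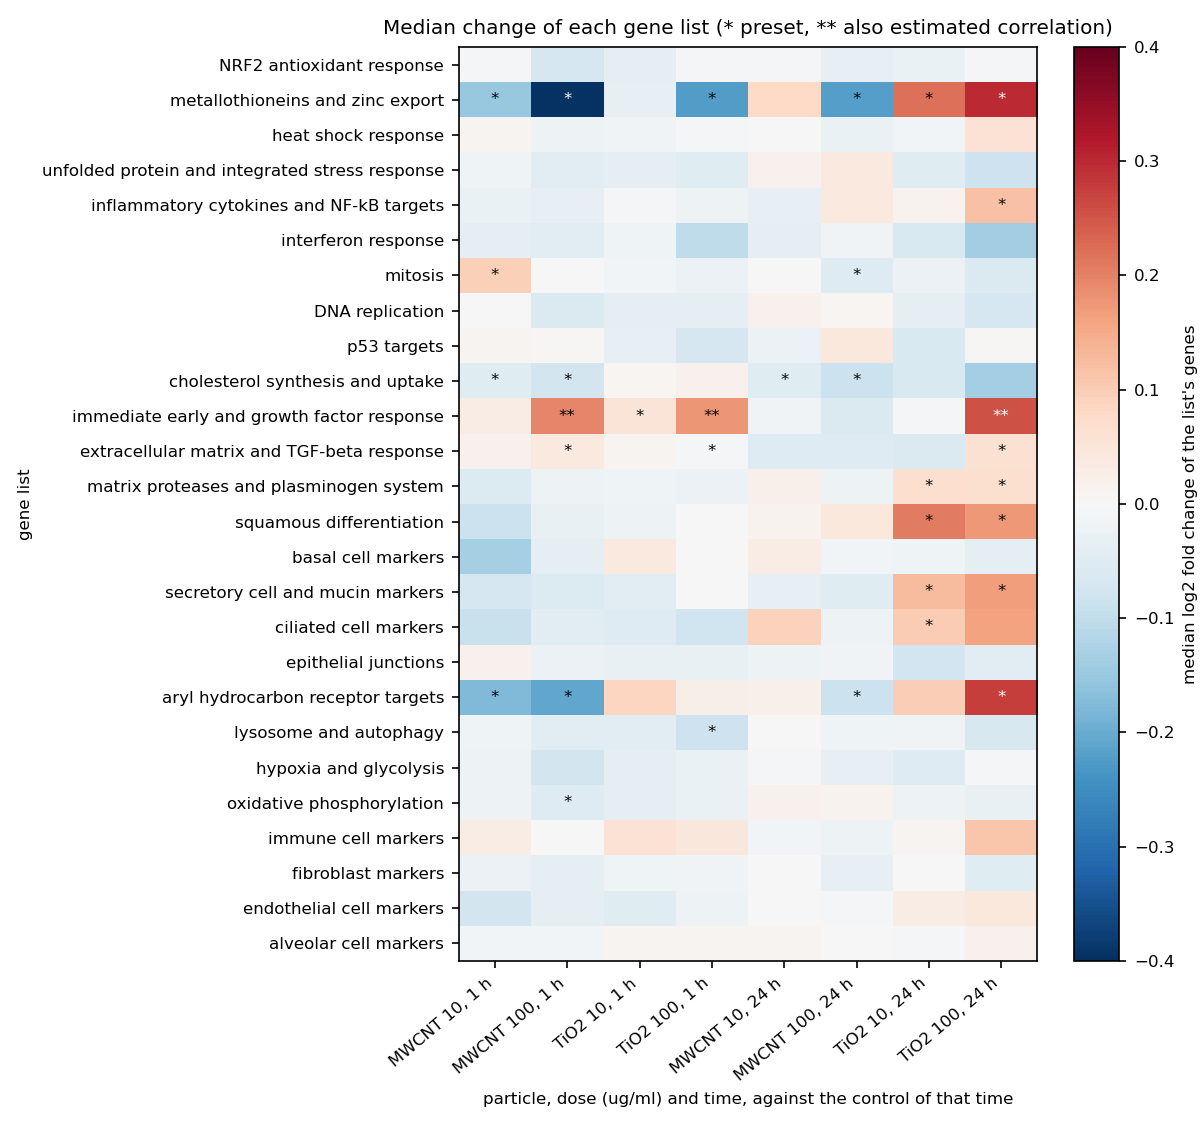
Colours give the median log2 change of each of the 26 gene lists (vertical) in the 8 comparisons of a particle with its control (horizontal), with 1 star for a list test passed at the preset correlation and 2 where it also passed with an estimated one. Immediate early genes carry 2 stars in MWCNT 100 and TiO2 100 at 1 h and in TiO2 100 at 24 h.

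The particles were also set against each other at 24 h. At 100 ug/ml, IER3 was lower with MWCNT than with TiO2 by 1.33 ± 0.08, at 7.29 ± 0.20 against 8.61 ± 0.18 (n = 3, adjusted p = 1.08e-10), ETV5 by 1.31 ± 0.10, ABCC3 by 1.01 ± 0.05 (adjusted p = 8.26e-12) and CYP1B1 by 1.57 ± 0.24. ID1, an inhibitor of differentiation factors, was lower by 0.91 ± 0.16, NRP1 by 0.90 ± 0.13 and the gel-forming mucin MUC5AC by 0.63 ± 0.13. ANO2 was higher by 0.82 ± 0.06, arginase 2 (ARG2) by 0.58 ± 0.08, the stress regulator NUPR1 by 0.54 ± 0.07 and the antiviral MX1 by 0.54 ± 0.12. THBS1 was lower by 0.75 ± 0.17, with other probe sets at -0.48 to -0.14. Altogether 1465 genes differed, 921 higher and 544 lower with MWCNT, 33 by more than 1.5-fold, and after cyclic loess 811, 311 higher and 500 lower, and 1178 higher and 309 lower with the filter on dim genes. The count was 898, 827 and 607 without MWCNT replicates 1, 2 and 3, and 809 and 788 without TiO2 replicates 1 and 3.

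In that comparison immediate early genes were lower with MWCNT, 15 of 27 with 1 higher, and 18 and 2 over the list alone (adjusted p = 1.86e-12, adjusted p = 0.000492 with an estimated correlation). Metallothioneins had 6 of 8 lower, 6 over the list alone, with MT1X by 0.70 ± 0.11 (adjusted p = 3e-07, adjusted p = 0.246 with an estimated correlation). AhR targets had 4 of 8 lower, 4 over the list alone, with TIPARP by 0.74 ± 0.08 (adjusted p = 5.29e-06, adjusted p = 0.133 with an estimated correlation). Matrix genes had 5 of 21 lower, 5 over the list alone, with CCN2 by 0.50 ± 0.07 (adjusted p = 0.000563, adjusted p = 0.165 with an estimated correlation), and proteases 3 of 16, 4 over the list alone (adjusted p = 0.019, adjusted p = 0.353 with an estimated correlation). Secretory markers had 4 lower and 1 higher of 13, and 5 and 1 over the list alone (adjusted p = 0.0106, adjusted p = 0.246 with an estimated correlation). DNA replication had 4 of 25 higher, 6 over the list alone, with CDC45 by 0.27 ± 0.06 (adjusted p = 0.0424, adjusted p = 0.165 with an estimated correlation). After cyclic loess the protease, secretory and DNA replication lists did not pass, with 1 DNA replication gene called there and 0 with only the compared groups in the fit.

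At 10 ug/ml for 24 h, the secreted scavenger receptor DMBT1 was lower with MWCNT than with TiO2 by 0.51 ± 0.09 (n = 3, adjusted p = 0.00738), the glycosyltransferase B3GNT4 by 0.51 ± 0.11 and MUC5AC by 0.58 ± 0.13, while DOHH, which modifies a translation factor, was higher by 0.40 ± 0.07. Squamous genes had 5 of 18 lower, 7 over the list alone (adjusted p = 0.000563, adjusted p = 0.246 with an estimated correlation), secretory markers 2 of 13, with 5 lower and 1 higher over the list alone (adjusted p = 0.00793, adjusted p = 0.246 with an estimated correlation), and proteases 2 of 16, 3 over the list alone (adjusted p = 0.0302, adjusted p = 0.386 with an estimated correlation), and none of these 3 lists passed after cyclic loess. There 1 squamous, 2 secretory and 1 protease gene were called, and with only the compared groups in the fit 0 of each. In all 584 genes differed, 245 higher and 339 lower, and after cyclic loess 206, 43 higher and 163 lower. The filter on dim genes turned this balance, with 313 higher and 79 lower, and only the compared groups in the fit gave 7 genes, all lower. Of the 339 lower genes, 19 had further probe sets with a mean above the median of the table. For these 19 the median change was -0.3168 on the tested sets and -0.0034 on the others. The count was 20 and 148 without MWCNT replicates 1 and 3, and 335, 343 and 138 without TiO2 replicates 1, 2 and 3. Across genes the effects of both particles at 24 h correlated at 0.336 at 10 ug/ml and 0.313 at 100 ug/ml, below the simulated means of 0.483 and 0.499 for unchanged groups and inside the simulated ranges, and genes are not independent replicates. At both doses 0 genes were called with both particles. Draws without change reached 640 higher and 443 lower at 10 ug/ml, and 445 and 339 at 100 ug/ml. The means were 11.69 and 6.3, and 5.3 and 4.33. Unchanged groups at 24 h can thus give many calls.

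Between the TiO2 doses at 24 h, IER3 was higher at 100 ug/ml by 1.10 ± 0.08, ETV5 by 1.06 ± 0.10, DUSP6 by 0.91 ± 0.13, ABCC3 by 0.82 ± 0.05 and the ERK feedback genes SPRED2, SPRY2 and DUSP4 by 0.74 ± 0.08, 0.53 ± 0.09 and 0.46 ± 0.10. KRT8, a simple-epithelial keratin, was lower by 0.60 ± 0.12, TNNC1 by 0.54 ± 0.10 and ANO2 by 0.53 ± 0.06, all chosen after their values were seen. In all 118 genes differed, 80 higher and 38 lower, 18 by more than 1.5-fold. The count was 77 and 75 without replicates 1 and 3 at 10 ug/ml, and 75 and 68 without replicates 1 and 2 at 100. Between the MWCNT doses at 24 h limma found 0 genes, with 268 at an unadjusted p under 0.05 and a smallest adjusted p of 0.871.

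Whether an effect differed between the times was tested at 100 ug/ml. With MWCNT the effect on EGR3 was lower at 24 h than at 1 h by 2.46 ± 0.25 (adjusted p = 1.97e-06), on NR4A1 by 1.84 ± 0.13 and on THBS1 by 1.56 ± 0.24, genes chosen after their values were seen. EGR3 lay between 3.64 and 4.51 in the 24 h arrays, under their lower quartiles (at least 5.3351) and so near background, where a change at 24 h is hard to measure. Of 80 genes, 14 were higher and 66 lower, 75 were changed at 1 h and 0 at 24 h. With TiO2 the effect on GLIPR1 was lower by 1.99 ± 0.24, though GLIPR1 still rose by 0.52 at 24 h (adjusted p = 0.0457). Of 263 genes, 120 were higher and 143 lower, 64 were changed at 1 h and 200 at 24 h, with 8 called at both times in opposite directions. The MWCNT count was 50 without control replicate 2 at 1 h and 50 without MWCNT replicate 3 at 1 h. For TiO2 it was 172 and 143 without control replicates 1 and 2 at 1 h, 143 without TiO2 replicate 3 at 1 h, 399 without control replicate 1 at 24 h, and 164 and 147 without TiO2 replicates 1 and 3 at 24 h.

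The unexposed cultures showed how expression moved without particles. From 1 to 24 h the ERK phosphatase DUSP5 fell by 5.29 ± 0.08, from 12.35 ± 0.11 to 7.06 ± 0.14 (n = 3, adjusted p = 1.36e-24), and EGR3 fell by 4.92 ± 0.17, a lower bound since its 24 h level of 3.98 is near background. The pseudokinase TRIB1 fell by 4.76 ± 0.10, the Notch target HES1 fell by 4.72 ± 0.10, DUSP6 fell by 4.70 ± 0.13 and CCN2 fell by 4.16 ± 0.07. ID1 and IER3 each fell by 4.10, and LIF, a cytokine, by 3.41 ± 0.11. CHAC1, which degrades glutathione under amino acid stress, rose by 2.45 ± 0.10 and PPP1R3C, of glycogen synthesis, by 1.65 ± 0.12. TIPARP fell by 2.51 ± 0.08 and CYP1B1 by 1.78 ± 0.24. In all 3796 genes changed, 2307 higher and 1489 lower, 546 by more than 1.5-fold.

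All 27 immediate early genes fell in the controls over time, by a median of 2.42, and 27 fell over the list alone (adjusted p = 1.31e-09 with an estimated correlation). The next lists passed at the preset correlation but not with an estimated one. Interferon genes had 14 of 25 higher, 16 over the list alone, with IFIT1 by 0.82 ± 0.10 (adjusted p = 6.84e-05, adjusted p = 0.0772 with an estimated correlation). Mitosis had 17 of 26 higher, 17 over the list alone, with MKI67 by 0.41 ± 0.06 (adjusted p = 6.81e-05, adjusted p = 0.168 with an estimated correlation), and DNA replication 10 higher and 1 lower of 25, and 11 and 2 over the list alone (adjusted p = 0.0197, adjusted p = 0.0772 with an estimated correlation). With only the compared groups in the fit 11 mitosis genes were higher, and 4 DNA replication genes were higher and 0 lower. AhR targets had 5 of 8 lower, 5 over the list alone (adjusted p = 6.84e-05, adjusted p = 0.0772 with an estimated correlation), and metallothioneins 7 of 8, 7 over the list alone, with MT2A by 0.84 ± 0.09 (adjusted p = 6.84e-05, adjusted p = 0.234 with an estimated correlation). Inflammatory genes had 10 lower and 2 higher of 26, and 11 and 2 over the list alone (adjusted p = 0.000818, adjusted p = 0.112 with an estimated correlation). Hypoxia genes had 7 lower and 1 higher of 20, also over the list alone, with ADM by 2.43 ± 0.08 (adjusted p = 0.00103, adjusted p = 0.0772 with an estimated correlation). Heat shock had 5 lower and 1 higher of 14, and 5 and 2 over the list alone, with DNAJB1 by 1.24 ± 0.07 (adjusted p = 0.0206, adjusted p = 0.168 with an estimated correlation). The p53 targets had 8 lower and 4 higher of 17, and 9 and 5 over the list alone (adjusted p = 0.0197, adjusted p = 0.31 with an estimated correlation). Cholesterol genes had 6 lower and 3 higher of 16, also over the list alone (adjusted p = 0.0197, adjusted p = 0.392 with an estimated correlation), with adjusted p = 0.0891 without control replicate 1 at 24 h.

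In the comparisons with controls, the lists of the NRF2, heat shock, stress and interferon responses, DNA replication, p53 targets, hypoxia, basal cells, junctions and immune, fibroblast, endothelial and alveolar cells passed at no dose or time. For basal cell markers, adjusted p with TiO2 at 100 ug/ml for 24 h was 0.941, with KRT5 lower by 0.24 ± 0.08 as the 1 of 11 called (0 over the list alone), a median of -0.0401 and a test that pointed up. For epithelial junctions it was 0.783, with 2 of 14 lower, and 1 higher and 3 lower over the list alone. For immune cells adjusted p was 0.24, fibroblasts 0.906, with FBN1 lower by 0.33 ± 0.05 and DCN higher by 0.41 ± 0.12 (1 higher and 2 lower over the list alone), endothelium 0.496 and alveolar cells 0.906, with LAMP3 lower by 0.33 ± 0.11 (2 lower over the list alone), a median of 0.0178 and a mean of -0.0101. The heat shock list gave 0.201, with HSPE1 higher by 0.18 ± 0.05 (1 higher over the list alone). For DNA replication it was 0.149, p53 targets 0.644, hypoxia 0.906, with ENO2 lower by 0.28 ± 0.05 (1 higher and 3 lower over the list alone), and unfolded protein response 0.499. Without control replicate 1 KRT5, DCN, LAMP3 and HSPE1 did not pass.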

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

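Chosen after the result was seen were the tests of cyclic loess, of interquartile range and of shared genes against draws without change for TiO2 at 24 h, and the tests of other probe sets, of ACTB and of dose for the 1 h rises with TiO2.

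The effect of MWCNT at 100 ug/ml differed between the times for 80 genes, by a test of the difference itself. For EGR3 the effect at 24 h minus that at 1 h was -2.46, for GLIPR1 -2.21, for FILIP1L -1.89, for NR4A1 -1.84 and for THBS1 -1.56. With TiO2 at 100 ug/ml it differed for 263 genes: GLIPR1 -1.99, EGR3 -1.85, FILIP1L -1.79, ANKRD1 -1.7 and NR4A1 -1.35. EGR3 (3.64 to 4.51) lay below the lower quartiles of the arrays (5.3351 to 5.4684) at 24 h, and ANKRD1 (4.67 to 5.5) near or below them, so their differences of effects do not measure a response lost by 24 h. Among 100 splits of the arrays within each time, 7 gave at least 80 genes for MWCNT (highest other 141) and 5 at least 263 for TiO2 (highest other 1147), so chance was not excluded for these counts. The highest split in both cases parted the real groups with 1 time turned round, which adds the effects at the times instead of subtracting them, a structure of the samples that the counts share.

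Probe sets with no gene symbol or with several, which the reported comparisons left out, also changed against the controls. These counts come from a fit other than that of the 11963 genes. There were 29 with MWCNT 100, 25 with TiO2 10 and 54 with TiO2 100 at 1 h, and 149 with TiO2 10 and 290 with TiO2 100 at 24 h.

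Many small changes stood out with TiO2 at 24 h, where risers had a median level of 6.521 and fallers of 8.962, so a shift with intensity is a candidate cause. After cyclic loess 648 of the 1577 genes (41.1%) stayed called in the same direction, 330 higher and 318 lower. For these 648, a shift that cyclic loess removes is argued against as the whole cause. The other genes, the larger part of the count, lost their call, and for them such a shift stays open. How many calls would stay under a shift alone was not simulated. The spread of the 24 h controls as the whole cause is argued against by a fit without controls, in which 1354 genes differed between TiO2 100 and MWCNT 100, 740 of them called in the same direction against the controls (6.67 on average and at most 502 in 100 draws with no difference between the particles, where both comparisons share the TiO2 100 arrays as here). Of the 1577 genes, 99 also differed between the TiO2 doses in the same direction. In 100 such draws with no dose difference there were 5.02 on average, and 1 draw reached 99 (303). A shift equal in all TiO2 arrays gives no difference between doses, and the 99 were picked for such a difference. That it is not their whole cause follows from the picking and is no separate evidence. Handling that differed between the dose groups was not tested. Of the 99, 2 were also called with TiO2 at 10 ug/ml against controls, so the changes at that dose are hardly covered. For the other genes exposure and handling cannot be told apart, since the interquartile ranges of the TiO2 24 h arrays all lay below those of the other 24 h arrays, by at least 0.0473.

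Of the 84 genes that rose with TiO2 at 10 ug/ml after 1 h, 31 had other probe sets above the median of the table, which moved by 12.5% as much (0.0905 against 0.7257), and 53 could not be tested so. Signal of single probe sets stays open as a cause. With the mean of their probe sets 18 of the 31 were still called. That mean includes the tested probe set, so this cannot count against the cause. With more than 1 probe set at any level there were 46 genes, of which 22 were still called. The 31 genes had 46 other probe sets, of which 9 were called higher. The share of the change seen on other probe sets ran from 1.1% (genes lower with MWCNT 10 than TiO2 10 at 24 h) to 102.8% in other comparisons. RNA degradation in the 1 h controls stays open too. The 3' minus 5' difference for ACTB differed by 0.0025 between the groups, with overlap (controls 0.2684 to 0.421, TiO2 0.3186 to 0.3465). Single arrays went both ways. Replicate 1 of the 24 h controls, low on these genes, had the highest of the 30 arrays at 0.8557. Replicate 3 of TiO2 100 at 1 h had the highest of the 1 h arrays at 0.5308 but was high on these genes, at 0.2527. Replicate 2 of the 1 h controls had 0.2684 but was low on them, at -0.6534. Exposure stays open. Of the genes 54 were also higher with MWCNT 100 and 80 with TiO2 100. These comparisons share the 1 h controls against which the genes were chosen, so the agreement is partly built in and does not decide it. The median difference of the genes between the TiO2 doses was 0.0688. In the controls over time 65 of the 84 were higher too, by a median of 0.6555, again against the same 1 h controls. The 1 h controls stood at -0.8423, -0.6534 and -0.4597 on these genes, in part because the genes were chosen as higher than them. Replicate 1 of the 24 h controls stood at -0.5153 and the other arrays at or above -0.2969.

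Lower AhR targets with MWCNT at 1 h were not explained by a shift with intensity, since 4 of the 4 called falls stayed called after cyclic loess. An effect of MWCNT that grows with dose was not decided: the list's median difference between 100 and 10 ug/ml was -0.0464, with 0 members called.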

How the results depend on the processing

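The mean of a gene's probe sets, the pairing of cyclic loess with leaving out replicate 1 of the 24 h controls, the list tests after cyclic loess and without that array, and the overlap without single arrays were chosen after the data were examined; the other alternatives were planned. Counts below are changed genes, M is MWCNT, T is TiO2, and 10 or 100 is the dose. Where a cause is not named it was not tested, and values near background, below the table's median, limit what small changes can show.

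Array weights gave 13 for M 10, 353 for M 100 and 195 for T 10 at 1 h, 8 for M 10, 722 for M 100, 2170 for T 10 and 3081 for T 100 at 24 h, 260 and 5 for M against T at 10 and 100 at 1 h, 1284 and 3095 for the same at 24 h, 118 (M) and 68 (T) between doses at 1 h, 1 (M) and 283 (T) at 24 h, and 405 (M) and 634 (T) for the effects between times. With weights the higher and lower counts were 205 and 148 for M 100 at 1 h, 164 and 31 for T 10 at 1 h, 216 and 115 for T 100 at 1 h, 55 and 13 for the T doses at 1 h, 162 and 121 for them at 24 h, and 243 and 162 for M between times. The weights of the 24 h controls were 0.3083, 0.4084 and 4.8691, so 1 array dominated that group.

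Only the compared groups in the fit, with fewer arrays to estimate the spread, gave 1 for M 10, 84 for M 100, 53 for T 10 and 105 for T 100 at 1 h. At 24 h it gave 0 for T 10 and 16 for T 100. For M against T at 10 it gave 4 at 1 h and 7 at 24 h. Between doses it gave 38 (M) and 11 (T) at 1 h, and 30 (T) at 24 h. It gave 2075 for the control over time, and 32 (M) and 46 (T) between times. M against T at 100 at 24 h gave 1354 in such a fit, so fewer arrays alone do not account for the 16 with T 100. The 24 h controls correlated with their own group at 0.9952 to 0.9969, and the exposed 24 h arrays at 0.9976 or more. What caused the losses was not tested. All probe sets, a larger number of tests, gave 323 for M 100, 283 for T 10 and 585 for T 100 at 1 h, 2 and 4 for M against T at 10 and 100 at 1 h, and 6194 for the control over time. Cyclic loess gave 177 for T 10 and 803 for T 100 at 24 h, 3 for M against T at 10 at 1 h, and 206 and 811 for M against T at 10 and 100 at 24 h. With it and without replicate 1 of the 24 h controls, T 10 and T 100 gave 24 and 473. The filter on dim genes gave 2 and 8 for M against T at 10 and 100 at 1 h, and 178 for the T doses at 24 h. The intensity trend and robust variance gave 7 for M against T at 100 at 1 h. The mean of a gene's probe sets gave 130 for T 10 at 1 h (127 higher, 3 lower), 61 of them shared with the 85. The other counts under these settings and under the replicate block lay within 1.5 times the reported ones.

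Leaving out 1 array gave 2 to 16 for M 10, 91 to 210 for M 100, 14 to 113 for T 10 and 143 to 374 for T 100 at 1 h. At 24 h it gave 0 to 0 for M 10, 0 to 1 for M 100, 74 to 956 for T 10 and 718 to 1513 for T 100. For M against T it gave 1 to 1 at 10 and 2 to 2 at 100 at 1 h, and 20 to 798 at 10 and 607 to 1061 at 100 at 24 h. Between doses it gave 40 to 60 (M) and 21 to 29 (T) at 1 h, and 0 to 0 (M) and 68 to 135 (T) at 24 h. For the control over time it gave 3198 to 3892, and between times 50 to 105 (M) and 143 to 399 (T). The correlation of the particles' effects ran from 0.4669 to 0.6406 at 10 and from 0.6474 to 0.7973 at 100 at 1 h, and from 0.1118 to 0.545 at 10 and from 0.264 to 0.4647 at 100 at 24 h.

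Of 427 calls of named genes, 23 were lost with all probe sets, 15 with array weights, 79 after cyclic loess, 9 with the intensity trend and robust variance, 65 with the mean of probe sets, 217 with only the compared groups and 11 with the replicate block, all without a change of direction, and 0 of 372 with the dim filter. Leaving out 1 array lost 692 of 2562. The 1 reversal was PLCB1, a phospholipase, with T 10 at 24 h: lower by 0.42 on the tested probe set, and 0.03293 higher (adjusted p = 0.8) as the mean of its probe sets. Its adjusted p was 0.0403 as reported. Of the 61 list calls, 6 held with an estimated correlation, 35 with fry, 45 after cyclic loess and 59 with the replicate block, which lost oxidative phosphorylation with M 100 at 1 h (0.0526) and AhR targets with M 100 at 24 h (0.0566). Without replicate 1 of the 24 h controls 33 of 39 held.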

Other observations

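The tests of other splits below were planned, and the genes in the next paragraph were chosen after their values were seen.

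TIPARP and CYP1B1, 2 AhR targets, were compared at 100 ug/ml. TIPARP stood at -0.83 with MWCNT and 0.33 with TiO2 at 100 ug/ml after 1 h, and at -0.20 and 0.54 after 24 h. CYP1B1 stood at -1.03 and 0.60 after 1 h, and at -0.30 and 1.28 after 24 h. The MWCNT values at 24 h did not pass (adjusted p = 0.893 and 0.986), nor did CYP1B1 with TiO2 at 1 h (adjusted p = 0.3). Without replicate 1 of the 24 h controls CYP1B1 stood at -0.7868 (adjusted p = 0.123) and 0.7873 (adjusted p = 0.00392) after 24 h. The AhR list between the particles had adjusted p = 5.29e-06, and adjusted p = 0.133 with an estimated correlation at 100 ug/ml and adjusted p = 0.147 at 10 ug/ml after 24 h. HES1 is a Notch target that fell by 4.72 in the controls over time. At 24 h it was higher with TiO2 at 100 ug/ml than in controls by 0.95 (adjusted p = 5.13e-06). At 10 ug/ml it stood at 0.13 and did not pass (adjusted p = 0.427).

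Each comparison of 3 arrays with 3 was set against the other splits of its 6 arrays, 10 splits in all, too few for a share under 0.05. In the following, the real count comes first and the highest of the other splits second. At 1 h MWCNT 10 gave 8 and 3, MWCNT 100 gave 203 and 0, TiO2 10 gave 85 and 0, and TiO2 100 gave 254 and 0. At 24 h MWCNT 10 gave 0 and 1, MWCNT 100 gave 0 and 91, TiO2 10 gave 724 and 2, and TiO2 100 gave 1577 and 0. For MWCNT against TiO2 the counts were 1 and 0 at 10 ug/ml and 2 and 33 at 100 ug/ml after 1 h, and 584 and 1 at 10 ug/ml and 1465 and 0 at 100 ug/ml after 24 h. Between doses they were 76 and 0 (MWCNT) and 35 and 0 (TiO2) after 1 h, and 0 and 1 (MWCNT) and 118 and 0 (TiO2) after 24 h. For the control over time they were 3796 and 121. In each comparison 1 split, the real one, reached the real count, except that all 10 reached it where it was 0, and 3 of the 10 reached 2 for MWCNT 100 against TiO2 100 after 1 h. Where the real count was 2 another split gave 33, and where it was 0 another gave 91, which points to a structure of those arrays. What separates them was not tested.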
